A study of Homo sapiens with 6 samples.

How the data were processed

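RNA-seq was measured in 6 libraries of the human hepatocellular carcinoma line JHH-4, 3 from control cells and 3 from cells made to overexpress miR-885-5p from a plasmid. Per the labels' protocols, total RNA was extracted with a column kit and libraries were built with an Illumina kit of the NEBNext Ultra RNA series; whether strand was kept is not given in the sources used here. The submitters' processing notes name HISAT2 2.0.4, StringTie 2.2.1, DESeq2 1.38.3 and the build GRCh38, with no role or order; the counting tool and the annotation release are not given in the sources used here. Per the file headers, the deposited table holds a count per gene and library, which is a whole number throughout and carries no normalization. Per the file headers, the authors also gave an FPKM value per gene and library, which was not used here in any test. The authors' deposited table further holds a p-value and a log2 fold change per gene for miR-885-5p over control, with no test named in the headers.

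The table has 14034 rows, of which 12420 carry an Ensembl gene ID and 1614 are new gene models with no gene name. All 12420 IDs were found in GENCODE 29 on GRCh38, 12415 as protein-coding genes and 5 as polymorphic pseudogenes. Every row reached 1 CPM (counts scaled by library total) in at least 3 libraries and the smallest sum over the 6 libraries was 194, so weakly expressed genes had been left out before deposit by a rule not given in the sources used here. How reads shared between near-identical genes were counted is likewise not given, so values of histone genes, of HSPA1A and HSPA1B, and of EEF1A1 and ribosomal protein genes, which have many processed pseudogenes, are uncertain. Without strand, reads of overlapping antisense genes cannot be separated. Total counts ran from 46382314 to 56409821 per library. Counts of replicates differed by more than sampling noise, with a chi-square per degree of freedom from 7.95 to 40.5 within groups and from 96.0 to 136 between them.

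Groups and replicate numbers were taken from the sample titles. The counts were tested with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood F test, TMM scaling, filterByExpr filter, which removed 0 genes), with Benjamini-Hochberg adjustment over all 14034 genes and a threshold of 0.05 on the adjusted p. Levels are given as TMM-scaled CPM, mean ± SD over 3 libraries, and log2 fold changes are miR-885-5p over control with their standard errors (SE). Of 30 gene lists, 29 had at least 3 tested members and were tested as 1 family with camera in limma 3.58.1 on log2 CPM (prior count 2, preset correlation 0.01, two-sided, Benjamini-Hochberg), with camera at an estimated correlation and fry beside it. The list of the microRNA locus and its host gene was not tested. The lists, the design, most alternatives and the rule for named genes were fixed before the data were examined. That rule takes MIR885 and its host gene ATP2B2; the 10 genes with the largest rise and the 10 with the largest fall among genes with a name past the threshold with a mean of at least 5 CPM and groups that do not overlap; 5 targets named in earlier literature; from each list the members with the smallest adjusted p (6 for the cell cycle lists and CDK inhibitors, 4 for other lists past the set test, 2 for the rest); and the 5 genes with an 8mer site and the largest fall. Other genes named in the text were chosen after their values were seen, and the values of some genes are not reported here.

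Seed sites of miR-885-5p were searched in the longest annotated 3′ UTR of each gene, which 12304 genes had: the 8mer GTAATGGA, the 7mer-m8 GTAATGG, the 7mer-A1 TAATGGA and the 6mer TAATGG, with CGCTGCC for the 3p arm. All heptamers found in at least 100 UTRs were ranked by the standardised difference in log2 fold change between genes with and without them, after a linear fit on log2 UTR length and GC content. The plan had named the difference itself, so that rank is also given for GTAATGG. Genes with a position were also grouped along each chromosome into windows of 51 neighbours, and each chromosome was divided at the widest gap between tested genes. The median of each side with at least 51 genes was compared with 10000 random gene sets of its size, with Benjamini-Hochberg adjustment over 41 sides; this was added after the fold changes had been seen.

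The alternatives were DESeq2 1.42.0, limma-voom, 3 other scalings, no filter and a filter at 1 CPM, the replicate number as a block, a test against a 1.5-fold change, an estimated correlation, other site definitions and leaving out each library. A filter at 5 CPM, the genes with a name alone and the genes off chromosome 1 were added after the data were seen. The fits were tested on simulated counts drawn from the means, dispersions and totals of these libraries for all 14034 genes: of 50 genes changed by each size, edgeR recovered 13 at 1.2-fold, 36 at 1.5-fold, 43 at 2-fold and 50 at 4-fold, with 16 calls among 13834 unchanged genes. Few genes were changed in that simulation, while 52.9% were called in these libraries, so its recovery rates need not hold for them.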

Results

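JHH-4 is an established cell line from a human hepatocellular carcinoma. Its messenger RNA was counted in 3 control libraries and in 3 libraries of cells that overexpressed miR-885-5p from a plasmid with the primary microRNA. Total counts over 14034 genes were 48392786, 48327113 and 49694754 in control libraries 1 to 3 and 46382314, 56409821 and 51664526 in miR-885-5p libraries 1 to 3. The submitters call the 3 libraries of a group technical replicates, so every p-value measures only the spread between such replicates. What the control cells received is not given in the sources used here, so effects of the plasmid or its delivery were not separated from those of the microRNA. The first principal component held 66.0% of the variance and separated the groups, and the second set control library 3 apart from the other libraries.

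MIR885 lies on chromosome 3 from 10394489 to 10394562 on the minus strand (GRCh38), inside an intron of ATP2B2 in 13 annotated transcripts. Neither MIR885 nor ATP2B2 was analysed here, so the overexpression itself was not checked. The mature 5p arm starts at base 11 and the 3p arm at base 43 of the 74-base annotated hairpin.

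The comparison asked which messenger RNAs differ when miR-885-5p is raised. Among genes with a name and a mean of at least 5 CPM, SPON2, which encodes a secreted matrix protein, rose most, from 3.08 ± 0.401 to 33.9 ± 2.02 CPM (n = 3 per group; log2 fold change 3.46, SE 0.10). DNER, a Notch-pathway receptor, rose by 3.34, G0S2, an inhibitor of triglyceride lipase, by 2.94, the collagen-binding integrin gene ITGA11 by 2.58 and TDO2, the hepatic tryptophan dioxygenase, by 2.37 on the log2 scale. The other genes among the 10 with the largest rise at that level were MYADM, DTX3, APCDD1L, PDE1C and IGFN1. At the same level CLVS1 fell most, from 9.44 ± 1.23 to 0.649 ± 0.325 CPM (log2 fold change -3.83, SE 0.30). HABP2, a secreted protease, fell by 2.95, the sphingosine 1-phosphate receptor gene S1PR3 by 2.25 and the ligand gene WNT7B by 2.14, the last from 135 ± 1.76 to 30.6 ± 2.67 CPM. FGB, a fibrinogen gene, fell from 20.7 ± 1.03 to 4.48 ± 0.757 CPM. UPK1B, CACNA2D3, ELFN2, KLHDC7A and COL5A1 completed the 10 with the largest fall at that level; weaker genes, such as GLI3 at 4.85 and CCL2 at -3.22 (chosen after their values were seen), had larger changes than most of these. Each of these 20 genes had an adjusted p of 1.51e-05 or lower in the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment.

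In all, 3697 genes were higher and 3726 lower with miR-885-5p, which is 52.9% of those tested. Most of these differences were small, with a median absolute log2 fold change of 0.39 among called genes. At least 2-fold differences were found for 437 genes above and 321 below control, or 758 together, of which 355 and 248 had a gene name. The groups did not overlap for 60.5% of all genes, against the 10% that chance gives for 3 against 3. The authors' deposited table gave p under 0.05 for 4047 genes above and 4045 below control, and none of the genes called here had the opposite sign there. A test against a 1.5-fold change called 493 genes higher and 410 lower, and with at least 5 CPM in 3 libraries the count at 2-fold was 362.

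The title of the series names cell cycle progression, so lists of G1/S, DNA replication and G2/M genes were tested first. All 40 DNA replication genes fell with miR-885-5p, by 0.27 to 1.33 on the log2 scale (mean log2 fold change -0.74, SD 0.25 across genes). MCM2, a subunit of the replicative helicase, fell from 343 ± 4.86 to 186 ± 4.63 CPM (log2 fold change -0.89, SE 0.04). RRM2, the small subunit of ribonucleotide reductase, fell by 0.97, thymidylate synthase (TYMS) by 0.95, the licensing factor gene CDC6 by 0.93, MCM4 by 0.88 and UHRF1, which maintains DNA methylation, by 1.00. Of 17 G1/S genes, 14 fell and 1 rose (mean log2 fold change -0.46). E2F2 fell from 23.7 ± 1.37 to 7.40 ± 0.727 CPM and CDK6 from 604 ± 16.9 to 309 ± 3.64 CPM, with log2 fold changes of -1.67 and -0.97. CDC25A, the phosphatase that activates CDK2, changed by -0.86, cyclin D3 (CCND3) and CDK2 by -0.77 each and E2F1 by -0.68. The member that rose was RBL2, a pocket protein that represses E2F target genes, at 0.51 (SE 0.06).

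Among 42 G2/M and mitosis genes 36 fell and none rose (mean log2 fold change -0.37, SD 0.23), while 6 were not past the threshold. CDCA8, a subunit of the chromosomal passenger complex, changed by -0.91, KIF2C by -0.76, CDC20, the activator of the anaphase-promoting complex, by -0.74, KIF20A by -0.68, cyclin A2 (CCNA2) by -0.58 and topoisomerase TOP2A by -0.47. CDCA8, KIF2C, CDC20 and E2F2 lie on the short arm of chromosome 1, where most genes were lower. The camera test gave adjusted p = 5.93e-18 for DNA replication, 1.30e-09 for G2/M and 5.25e-04 for G1/S. None of the 3 calls held with an estimated correlation, where adjusted p = 0.0656, 0.123 and 0.105 with an estimated correlation. Adjusted over the list alone, the counts were the same, with 40, 36 and 14 genes lower.

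**Figure D1:**
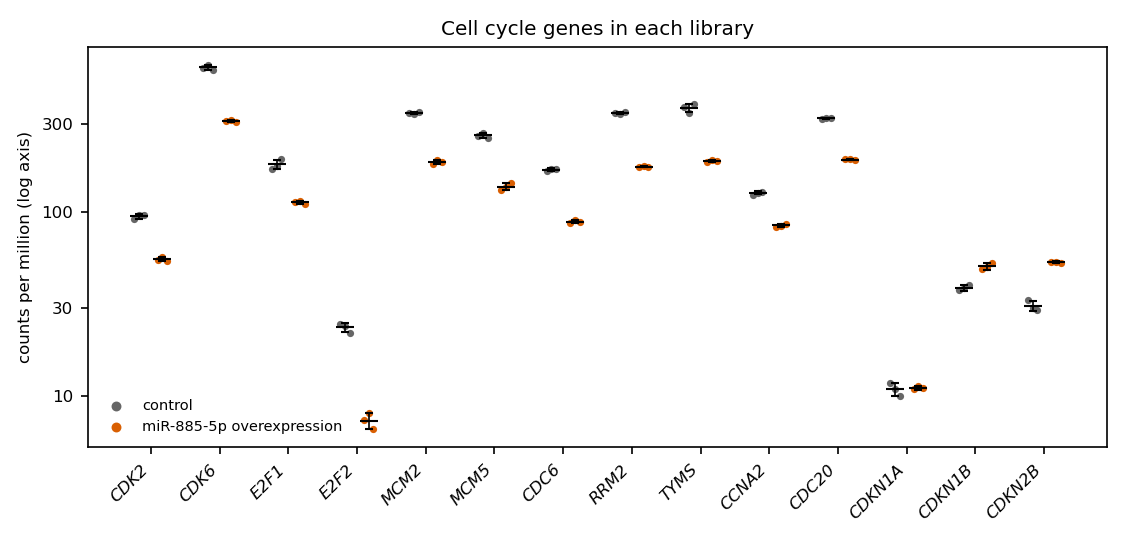
CPM (log axis) of 14 cell cycle genes, with 1 point per library in grey for control and orange for miR-885-5p overexpression, and bars for mean and SD (n = 3 per group). For genes from CDK2 to CDC20 every miR-885-5p library lies under every control library, CDKN1A overlaps, and CDKN1B and CDKN2B lie above control.

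CDK inhibitors went both ways. CDKN2B, which encodes the CDK4 and CDK6 inhibitor p15, rose from 30.9 ± 1.98 to 53.2 ± 0.547 CPM (log2 fold change 0.78, SE 0.06) and CDKN1B, which encodes p27, rose by 0.39 (SE 0.05). CDKN2C fell by 0.32, and CDKN1A, the p21 gene and a p53 target, had a log2 fold change of 0.03 (SE 0.09, adjusted p = 0.786). CDKN2A and CDKN2D had values of -0.11 and 0.08 and did not pass the threshold, except that CDKN2A passed it without miR-885-5p library 2 (log2 fold change -0.14, adjusted p = 0.0386). Over the 6 tested members camera, which compares the list with other genes, gave adjusted p = 0.546, and fry, which asks whether the list moves one way, gave adjusted p = 0.00624, upward. Of 28 p53 target genes, 8 rose and 11 fell, among them AEN at -1.33 and the kinase gene PLK2 at -0.52, with adjusted p = 0.474 for the list. In the list of BCL2 family and apoptosis genes 5 of 20 rose and 7 fell (adjusted p = 0.753), and the pro-apoptotic genes BBC3 and BMF rose by 1.21 and 0.79.

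Of 5 genes that earlier literature names as targets of miR-885-5p, 4 fell. MCM5, a subunit of the replicative helicase, fell from 259 ± 8.37 to 137 ± 6.26 CPM (log2 fold change -0.92, SE 0.04) and CDK2 from 94.5 ± 2.97 to 55.5 ± 1.41 CPM (log2 fold change -0.77, SE 0.04). HK2, a hexokinase, changed by -0.26 and CTNNB1, the beta-catenin gene, by -0.14, while CPEB2, a regulator of translation, rose by 0.54 (SE 0.07). The call of CTNNB1 (adjusted p = 0.0317) was lost under total-count scaling, upper-quartile scaling, the replicate block and without control library 3 or miR-885-5p library 1 or 3, with adjusted p from 0.0551 to 0.16 there. The list's adjusted p in camera was 0.115, and 0.0164 with DESeq2, but 0.294 in the main fit with an estimated correlation. The longest annotated 3′ UTRs of CDK2, MCM5 and HK2 held 0 sites of the 7mer-m8 or 8mer type, that of CTNNB1 held 2 and that of CPEB2 held 1.

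Genes with seed sites were compared with genes without a 7mer site. The 312 genes whose 3′ UTR holds the 8mer GTAATGGA had a mean log2 fold change of -0.13, against 0.03 for 10183 genes without a 7mer site, and 43.9% of them fell against 27.4%. WDHD1, a replisome component, fell from 47.1 ± 2.25 to 15.0 ± 1.05 CPM (log2 fold change -1.65, SE 0.07) and holds its 8mer at bases 54941459 to 54941466 of chromosome 14 (GRCh38), which starts at base 24 of a UTR of 2540 bases. The tight-junction gene CLDN1 fell by 1.31, with its 8mer at 190306682 to 190306689 of chromosome 3, and the nuclear receptor gene NR5A2 by 1.30, with its site at 200174469 to 200174476 of chromosome 1. The interleukin 6 receptor gene IL6R fell by 1.30 (site at 154468051 to 154468058 of chromosome 1) and ECE1 by 1.28 (site at 21217270 to 21217277 of chromosome 1). Among cell cycle genes, CDK6, E2F2 and CDCA8 each hold a 7mer-m8 site. These are 2 of 17 G1/S and 1 of 42 G2/M genes, and 0 of 40 DNA replication genes hold one. Of all genes with a 3′ UTR, 8.01% hold a 7mer-m8 or 8mer site.

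With the definition fixed in advance, 7mer-m8 or 8mer, 985 genes had a mean log2 fold change lower by 0.09 than genes without (difference -0.0851, SE 0.0160 across genes, which are not independent replicates), and camera gave p = 0.147 (p = 0.0879 with an estimated correlation). For 8mer genes alone the difference was -0.15 with p = 0.00337, and p = 0.0644 with an estimated correlation. In fry, which asks whether the set moves one way and not whether it differs from other genes, p was 5.08e-05 for the wider set. Genes with a site for the 3p arm differed by 0.03 from 11609 genes without it (camera p = 0.430, n = 695 genes with the site). The 1136 genes whose strongest site was a 7mer-A1 had a mean log2 fold change of 0.04, against 0.03 for 8559 genes with none of the sites. Among 15923 heptamers GTAATGG had the second lowest standardised difference after correction for UTR length and GC content (rank 2, 985 genes, corrected difference -0.0723). GGTCAGG, found in 2329 UTRs, ranked 1, TAATGGA ranked 3393 and the heptamer of the 3p arm ranked 4032. By the corrected difference itself, the measure planned in advance, GTAATGG ranked 47 of 15923.

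**Figure D2:**
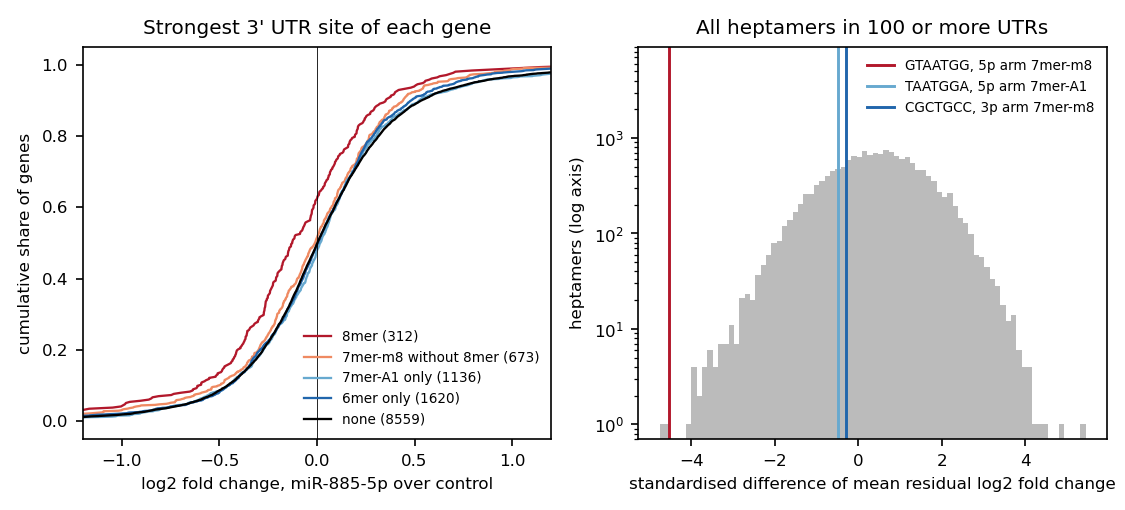
Left, cumulative share of genes by log2 fold change, each gene placed by its strongest site, with the number of genes in brackets; the 8mer curve (312 genes) lies to the left of the others. Right, histogram of the standardised difference of 15923 heptamers (count on a log axis), with lines at 3 heptamers; GTAATGG lies at -4.54 near the left end.

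Genes of cholesterol synthesis and uptake rose with miR-885-5p. Of 25 members 22 rose and 2 fell (mean log2 fold change 0.66, SD 0.69). HMGCS1, which makes the precursor of mevalonate, rose from 61.8 ± 4.24 to 193 ± 5.32 CPM (log2 fold change 1.64, SE 0.05), the sterol oxidase gene MSMO1 from 42.3 ± 2.28 to 120 ± 4.57 CPM, and by log2 fold change CYP51A1 rose by 1.06 and INSIG1, the sterol sensor partner, by 0.87. Of 13 fatty acid synthesis genes 8 rose and 1, ME1, fell (mean log2 fold change 0.39), with ACSS2 at 1.12, the desaturase genes SCD, FADS1 and FADS2 at 0.83, 0.74 and 0.63. The set tests gave adjusted p = 2.03e-09 for cholesterol and 0.00967 for fatty acid genes, and neither call held, with adjusted p = 0.0892 and 0.190 with an estimated correlation. Adjusted over the list alone, 23 cholesterol genes were higher and 2 lower, and 8 fatty acid genes higher and 1 lower.

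Replication-dependent histone genes, whose usual transcripts lack a poly(A) tail and are made in S phase, rose while the replication genes fell. Of 24 listed members 10 were tested. Of these 10 members 9 rose and none fell, and adjusted over the list alone 10 rose (mean log2 fold change 1.42, SD 0.43). HIST1H1C rose from 8.35 ± 0.467 to 26.7 ± 0.597 CPM (log2 fold change 1.68, SE 0.07), HIST1H2BD by 1.80, HIST1H2AC by 1.77 and HIST1H2BK by 1.39. The set test gave adjusted p = 2.42e-05, and adjusted p = 0.0892 with an estimated correlation. Reads of these near-identical genes may be split by the counting, so single values are uncertain.

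Ribosomal protein genes took 4.46 to 4.96% of counts in control libraries and 5.82 to 6.05% with miR-885-5p. Of 76 genes 61 rose and 2, RPS26 and RPS15, fell (mean log2 fold change 0.29, SD 0.21). The mean was above 0 under all 4 scalings, but a scaling moves all genes alike, so this decides nothing about the scaling. RPL3 rose from 1566 ± 67.1 to 2158 ± 49.8 CPM (log2 fold change 0.46, SE 0.04), RPL13 by 0.43, RPS20 by 0.41 and RPL4 by 0.32. Adjusted over the list alone, 62 were higher and 2 lower. The set test gave adjusted p = 7.39e-08, and adjusted p = 0.359 with an estimated correlation.

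Several stress and innate immune lists were lower. Of 14 heat shock genes 12 fell and none rose (mean log2 fold change -0.33), led by the chaperone gene HSP90AA1, which fell from 2358 ± 42.2 to 1321 ± 16.5 CPM (log2 fold change -0.84, SE 0.04). HSPA4L fell from 98.0 ± 2.62 to 58.9 ± 2.70 CPM, DNAJA1 changed by -0.36 and HSPH1 by -0.33 on the log2 scale. Of 29 interferon-stimulated genes 13 fell and 2 rose (mean log2 fold change -0.35), with BST2, which tethers virions, at -1.52, the 2′-5′ oligoadenylate synthetase gene OAS3 at -0.82, IRF7 at -0.76 and, upward, IFI44L at 0.60. Of 21 integrated stress response genes 11 fell and 4 rose (mean log2 fold change -0.19), where the amino acid transporter gene SLC7A5 changed by -0.67 and the biosynthetic genes ASNS, PSPH and PHGDH by -0.53, -0.53 and -0.51. The members that rose were TRIB3, CEBPB, DDIT3 and DDIT4. Set tests gave adjusted p = 2.70e-04, 0.0117 and 0.0490 for these lists, and adjusted p = 0.148, 0.146 and 0.359 with an estimated correlation. The call of the integrated stress response list also ended under the replicate block and without control library 3 or miR-885-5p library 1 or 3, where adjusted p ran from 0.0588 to 0.0888, without the new gene models (adjusted p = 0.0522), at 5 CPM (adjusted p = 0.0552) and without chromosome 1 (adjusted p = 0.145). Adjusted over the list alone, the counts of the 3 lists were the same.

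The remaining lists did not pass the set test with edgeR and camera. Of 30 listed hepatocyte genes 14 were tested, and ALB, APOB and HNF4A were not among them. Of the 14 tested genes 5 rose and 6 fell (adjusted p = 0.987): TDO2 was up as above, and the fibrinogen genes FGA, FGB and FGG, neighbours on chromosome 4, had log2 fold changes of -1.64, -2.20 and -1.44. Of 17 listed epithelial markers 11 were tested, without CDH1 and EPCAM. Among these 11 markers 1 rose and 6 fell (adjusted p = 0.0633), with the claudin genes CLDN4 at 2.05 and CLDN1 at -1.31. Among mesenchymal markers 7 of 15 rose and 3 fell (adjusted p = 0.269), with SNAI2 at 1.36 and THY1 at -0.75. Of 9 Wnt target genes 2 rose and 7 fell (adjusted p = 0.127), with the secreted Wnt antagonist gene DKK1 at -1.38 and glutamine synthetase (GLUL) at 0.55. Serum response genes had 11 of 21 higher and 5 lower (adjusted p = 0.0633), with DUSP4 at 0.88 and JUN at -0.70, and YAP/TAZ targets 5 of 16 higher and 6 lower (adjusted p = 0.921), with NT5E, which rose from 140 ± 8.29 to 320 ± 6.21 CPM, and CYR61 at -0.64. NF-kB genes had 4 of 16 higher and 4 lower (adjusted p = 0.888), with RELB at 1.11 and NFKB2 at 0.86. Glycolysis genes had 4 of 19 higher and 12 lower (adjusted p = 0.0984), with enolase ENO1 at -0.66 and ALDOC at 0.48, and hypoxia genes 6 of 19 higher and 6 lower (adjusted p = 0.987), with CA9 at -1.44 and PFKFB4 at 0.60. Endoplasmic reticulum chaperones had 3 of 18 higher and 11 lower (adjusted p = 0.0633), with calreticulin (CALR) at -0.46 and DNAJB9 at 0.93. In the microRNA pathway 2 of 13 genes rose and 5 fell (adjusted p = 0.318), among them AGO2 at -0.41, which holds an 8mer site, and DGCR8 at -0.32.

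Adjusted over the list alone, the counts of these lists were the same except for 12 p53 targets lower, 7 hypoxia genes lower and 6 microRNA pathway genes lower. Mean, median and set test differed in sign for the lists of hepatocyte, NF-kB, hypoxia, microRNA pathway, YAP/TAZ and leukocyte genes; the hepatocyte list, for example, had a mean of -0.16 and a median of 0.02. For BCL2 family genes camera and fry differed in direction. In the main fit, 0 of the 29 lists passed camera with an estimated correlation. With DESeq2 and the preset correlation, the lists of serum response, fibroblast and endothelial genes passed (adjusted p = 0.0321, 0.0206 and 0.0321). With limma-voom those of epithelial, endoplasmic reticulum chaperone, mitochondrial and fibroblast genes did (adjusted p from 0.0435 to 0.0476). Without control library 1 the fibroblast and endothelial lists passed (adjusted p = 0.0272 and 0.0361), without control library 2 the serum response list (adjusted p = 0.0382), and without chromosome 1 the Wnt and serum response lists (adjusted p = 0.0305 and 0.0263).

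Markers of other cell types were also measured, with 4 of 9 listed endothelial, 6 of 10 fibroblast and stellate cell and 3 of 12 leukocyte markers tested. Endothelial markers had 3 of 4 tested genes higher and none lower (adjusted p = 0.0633), with the TGF-beta co-receptor gene ENG rising from 4.22 ± 0.265 to 16.2 ± 1.63 CPM and TIE1 by 1.07 on the log2 scale. Fibroblast and stellate cell markers had 4 of 6 higher and none lower (adjusted p = 0.0633), with the receptor gene PDGFRB at 1.03 and RGS5 at 0.79. Leukocyte markers had 1 of 3 higher and 1 lower (adjusted p = 0.888), with CSF1R at 0.44 and CD14 at -0.83, the latter at a mean of 1.41 CPM in control. The call of CD14 was lost under total-count scaling and without control library 2 or 3 or miR-885-5p library 1 or 3, with adjusted p from 0.0524 to 0.133. Mitochondrially encoded messenger RNAs took 5.43, 6.37 and 4.45% of counts in control libraries 1 to 3 and 4.80, 4.46 and 4.82% in miR-885-5p libraries 1 to 3. Of these 13 genes 4 fell and none rose (mean log2 fold change -0.31, adjusted p = 0.0644), with MT-ND6 at -0.76 and MT-ND5 at -0.75. Without control library 3 the mean was -0.44 and the list passed, with adjusted p = 0.0018. With all libraries and an estimated correlation, camera gave adjusted p = 0.706 for this list.

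**Figure D3:**
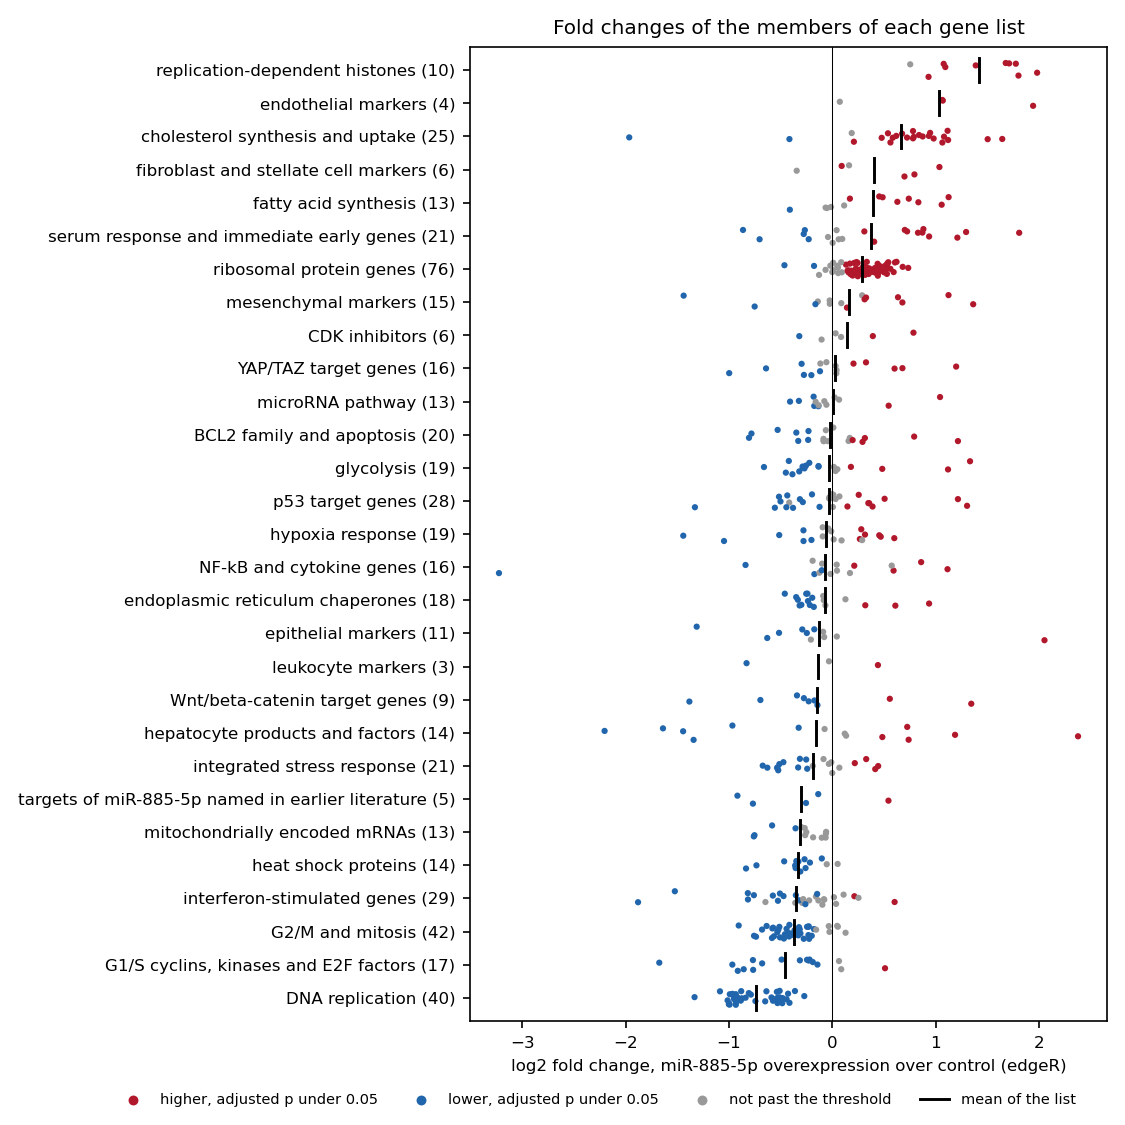
Log2 fold change of each member of 29 gene lists (number of tested members in brackets), in red for higher, blue for lower and grey for members not past an adjusted p of 0.05, with a black bar at the list's mean. All 40 DNA replication genes lie left of 0 and 9 of 10 histone genes are red.

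The fold changes were not evenly spread along the chromosomes, which was examined after they had been seen. On chromosome 1 the widest gap between tested genes runs from 121392822 to 143955364 and spans the centromere. Of 694 genes before the gap, on the short arm, 387 fell and 76 rose (median log2 fold change -0.23, quartiles -0.45 and 0.00), and of 575 genes after it, on the long arm, 99 fell and 271 rose (median 0.16, quartiles -0.06 and 0.40). Among all genes with a name 27.5% rose and 27.7% fell. Both medians lay farther from that of all genes than in any of 10000 random gene sets (permutation p = 0.0001, the smallest they can give; adjusted p = 5.86e-04 over 41 sides of chromosomes). Of the 41 sides, 13 had an adjusted p under 0.05, 5 of them low and 8 high, among them the part of chromosome 5 after base 31193750 at -0.14 and the part of chromosome 7 before base 56106576 at 0.14. Of genes named above, KLHDC7A, ECE1, E2F2, CDC20, CDCA8, KIF2C, CDKN2C, PHGDH, JUN, CYR61 and ENO1 fell and lie on the short arm of chromosome 1, while G0S2, IGFN1, GLUL and RGS5 rose and lie on its long arm. IFI44L and TIE1 rose on the short arm, and IL6R and NR5A2 fell on the long arm. Without chromosome 1 the counts were 3356 higher and 3187 lower. The list means were then -0.73 for DNA replication, -0.38 for G1/S and -0.38 for G2/M genes, all past the set test at its preset correlation. With all chromosomes these calls were lost in camera with an estimated correlation (adjusted p = 0.0656, 0.105 and 0.123).

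**Figure D4:**
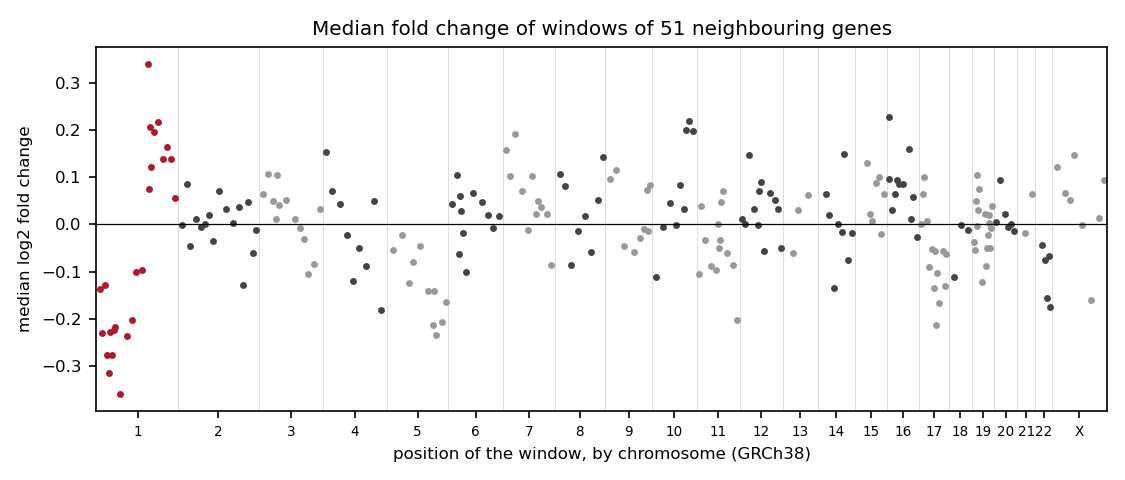
Median log2 fold change of 231 windows of 51 neighbouring genes by position and chromosome (GRCh38), with chromosome 1 in red and the others in alternating greys. The windows of the short arm of chromosome 1 lie under 0 and those of its long arm above it.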

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

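The filter at 5 CPM, the fit without new gene models and the fit without chromosome 1 were chosen only after the data were seen. The DNA replication, G1/S and G2/M lists stayed lower and past the threshold under DESeq2, limma-voom, 3 other scalings, the replicate block, each omission of 1 library and the 3 added settings. With an estimated correlation between genes none of these lists passed, with unchanged means of -0.74 (adjusted p = 0.0656), -0.46 (adjusted p = 0.105) and -0.37 (adjusted p = 0.123); that setting widens the error for genes that vary together. Leaving out 1 library at a time gave -0.75 to -0.73 for DNA replication, -0.47 to -0.45 for G1/S and -0.39 to -0.36 for G2/M genes. In camera the CDK inhibitors passed under no setting, while fry in the main fit gave adjusted p = 0.00624, upward.

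A test against a 1.5-fold change called 493 genes higher and 410 lower, since it asks for more than a difference from 0. At 5 CPM in 3 libraries 362 genes differed at least 2-fold, where fewer genes were tested. Total-count scaling gave 4357 higher and 3134 lower. DESeq2 shared 98.0% and limma-voom 99.1% of the edgeR calls. Leaving out 1 library gave 3101 to 3814 genes higher, 3182 to 3864 lower and 758 to 818 at least 2-fold. No filter and the filter at 1 CPM removed no gene, so these settings tested nothing.

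Replicate numbers did not pair the groups: deviations of libraries with the same number had correlations across genes of -0.12, -0.08 and -0.17. With the replicate block 3329 genes were higher and 3366 lower, and 89.3% of the calls were shared.

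The difference of genes with seed sites was -0.15 with 8mer sites only, which passed (camera p = 0.00337, n = 312 genes with the site) but not with an estimated correlation (p = 0.0644, n = 312 genes). For any 6mer match, 8mer genes included, it was -0.03 (camera p = 0.745, n = 3741 genes). Leaving out 1 library gave -0.09 to -0.08, none past the threshold. Of 1883 values for 112 named genes under alternatives, 1871 kept direction and side of the threshold, 11 lost the call, 1 gained it and 0 reversed. At this depth the simulated counts gave 13 of 50 calls at 1.2-fold, so small differences can be missed. That rate need not hold here, since 13834 of 14034 simulated genes were unchanged, while 52.9% of genes were called in these libraries.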

Other observations

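The tests on the arms of chromosome 1 and the means by chromosome were chosen only after the result was seen. Translation factors moved with the ribosomal proteins: EEF1A1 rose from 11514 ± 781 to 16513 ± 177 CPM, EEF2 from 2996 ± 11.7 to 3995 ± 13.3 CPM, and EIF3E, EIF3F and EIF4B by 0.41, 0.43 and 0.40 on the log2 scale (n = 3 per group, edgeR adjusted p of 2.31e-05 or lower). These messenger RNAs share a 5′ terminal oligopyrimidine tract with those of ribosomal proteins. Over 14 such mRNAs, listed before their values were examined except that EEF1A1 had been seen as the most abundant gene, 11 rose, 0 fell and EEF1D, NAP1L1 and RACK1 were not past the threshold (mean log2 fold change 0.2721, 95% interval 0.17 to 0.38 across genes). A shared change of this class of mRNA may be part of the ribosomal protein pattern, as a hypothesis.

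G2/M genes differed by place. CDC20, KIF2C and CDCA8, on the short arm of chromosome 1, had a mean log2 fold change of -0.80, and 34 members off chromosome 1 had one of -0.39, with 32 lower. KIF14, CENPF, NUF2, ASPM and NEK2, on the long arm, had a mean of -0.03 and 1 of the 5 was lower. Among DNA replication genes ORC1, CLSPN and RPA2 on the short arm had a mean of -0.93 against -0.73 elsewhere. These differences were not tested.

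DNA replication genes were lower in all 40 cases. Seed sites in their own 3′ UTRs are argued against as the cause, since 0% of the 40 genes held a 7mer-m8 or 8mer site (exact upper 95% bound 8.81%). A trend with transcript length or GC content is argued against by a mean residual of -0.7401 (95% interval -0.82 to -0.66). All 40 fell although they lie on 20 chromosomes, none with over 10.0% of them. Relative to the median of neighbouring genes their mean was still -0.72. Both values argue against a difference in copy number of these genes themselves. Whether copy number elsewhere in the genome affected them was not tested. A lower share of cycling cells through miR-885-5p may be the source, but any other difference between the 2 cultures, such as density, stays open and was not tested.

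Ribosomal protein genes were higher. A trend with length or GC content is argued against by a mean residual of 0.3047 (95% interval 0.25 to 0.36). The mean minus the median of all genes was at least 0.2884 under 4 scalings, but a scaling moves all genes alike, so this value decides nothing about the scaling, which stays open. Reads shared with processed pseudogenes were not tested, and a biological source likewise stays a hypothesis.

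Many genes differed. Of 243 genes lower at least 2-fold with a 3′ UTR, 33 or 13.5802% held a 7mer-m8 or 8mer site (exact 95% interval 9.54 to 18.5). That interval lies above the 8.01% of all genes with a 3′ UTR that held one, with no account taken of UTR length. Since most of the 243 genes held no such site, seed sites may account for few of them. A copy-number difference between the 2 cell populations cannot be told apart from other causes for the many genes that differed. The SD of window medians was 1.8478 times its mean over 1000 random gene orders, larger than in each of them (0.1065 against at most 0.0672), but under the factor of 2 set for that explanation and over the 1.2 set against it. On chromosome 1 all 13 windows of the short arm lay below 0 and all 11 of the long arm above it, and the 6 libraries divided by group, with medians of 0.11 to 0.12 in control and -0.13 to -0.11 with miR-885-5p on the short arm. Whether whole arms shifted also stays open, since window medians within an arm varied up to 1.5292 times as much as in random orders.

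In the 10 splits of the 6 libraries into 3 and 3, 1 split, the real one, gave a value as large for each result, and 10 splits cannot give a share under 0.05. The real split called 7423 genes against 0 in the highest other, and 758 against 0 at least 2-fold. The absolute mean was 0.4597 against 0.1572 for G1/S, 0.7436 against 0.2592 for DNA replication, 0.374 against 0.1538 for G2/M genes, and 0.0851 against 0.0358 for the difference of genes with seed sites.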
